A study of Cucumis sativus with 12 samples.

How the data were processed

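RNA of cucumber leaves was sequenced in 12 libraries, 3 from each of 4 durations of cold (0, 3, 12 and 24 h) after a chitosan oligosaccharide spray at 50 mg/L, per the labels. RNA was extracted with Trizol and sequenced as cDNA on an Illumina instrument, per the labels' protocols and the series design text. Adapters were trimmed with cutadapt 1.9 and reads were checked with FastQC, per the submitters' processing notes, and reads were mapped with HISAT2 to a cucumber genome of the CuGenDB site, per the series design text. The counting tool, the annotation release, the genome build and the strand setting are not given in the sources used here. Coordinates are whole-gene spans as the deposited table gives them, and genes that overlap another are named as uncertain.

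The estimated counts per gene were made by the authors and deposited as whole numbers, per the file headers, so that no rounding was needed. Low values lie near multiples of 3.73, so that a unit is not a read and the counting error is larger than the unit would give. The FPKM values were also made by the authors and deposited in the same table, per the file headers, scaled to transcript length and library size; 0.0001 stands there for each of 61048 estimated counts of 0 and was read as 0. Names, GO and KEGG terms were taken from the same table, which holds 24317 genes, 10054 of them without an informative description. Totals (M, 10 to the power of 6) were 67.6, 70.4 and 81.6 M units in the 0 h libraries, 63.5, 62.7 and 70.2 M at 3 h, 64.2, 74.3 and 65.2 M at 12 h and 77.9, 73.7 and 69.8 M at 24 h. The 10 most abundant genes held 6.98% to 9.49% of the counts.

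The design fixed beforehand assumed a table of FPKM and limma as the test, with edgeR in its place if counts were found. Since the table holds estimated counts, the test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, in 1 fit over all 12 libraries with a mean per duration and no block. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 16432 genes with 99.84% of the counts; 7885 were not tested. The biological coefficient of variation was 17.2%. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 within a comparison were called changed. Levels are given as mean FPKM ± SD of 3 libraries and log2 fold changes with their standard error from the edgeR fit.

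A total of 40 gene lists, including markers of epidermis, phloem, guard cells and roots, were fixed as patterns on gene descriptions before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Terms with 10 to 500 tested members were tested likewise against 11400 tested genes with a term. The genes named were chosen by a rule fixed at the same stage. For each comparison with 0 h it took the 6 largest rises and the 6 largest falls in log2(FPKM + 1) among called, described genes with a mean of at least 5 FPKM in the higher group and no overlap between replicates. It also took the member with the largest change from each of the 14 lists with most called members, under the same level.

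The procedure was tested on simulated data for the comparison of 3 h with 0 h, with 200 of 16432 genes changed, 50 at each size. The edgeR test recovered 1 of 50 genes changed by 1.25-fold, 15 at 1.5-fold, 31 at 2-fold and 45 at 4-fold, all in the right direction, with 9 false calls. DESeq2 recovered 10, 29, 41 and 47, with 36 false calls, and limma on log2(FPKM + 1) 1, 14, 32 and 46, with 7. In the real comparison 57.7% of genes were called. The adjusted threshold depends on the share of genes changed, so recovery and false calls do not carry over to it. For shared 0 h libraries, all 12 libraries were simulated 20 times from a common mean per gene, so that the error of the 0 h libraries enters every comparison.

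Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, other scalings (median of ratios, quantile, equal totals), the replicate number as a block, fits of only the groups compared, limma without trend and robust, an unadjusted p as the submitters state, a 2-fold threshold, and leaving out each library. Alternatives added after the data were seen were limma on log2(FPKM + 1) as first designed, DESeq2 1.42.0, and counts divided by 3.73. Library totals without TMM were run as the counterpart of the unscaled FPKM in the first design. Water-sprayed groups were not analysed here, and the clock time of sampling is not given in the sources used here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.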

Results

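Messenger RNA was measured by sequencing in fully expanded leaves of cucumber (Cucumis sativus) seedlings that had been sprayed with chitosan oligosaccharide (COS), short chains made from chitosan, at 50 mg/L. After 24 h the seedlings were moved from warm to cold conditions, and leaves were taken after 0, 3, 12 and 24 h of cold. Each of the 4 cold durations had 3 libraries, 12 in all. Water-sprayed seedlings were not analysed here, so the comparisons show how leaves of sprayed seedlings changed with time in the cold, and not what the spray did. Time since the spray, and plant age if all were sprayed at the same age, rose together with time in the cold. A continuing or fading effect of the spray can thus not be told apart from an effect of cold. The clock time of sampling is not given in the sources used here. The 0 h and 24 h leaves lie a whole day apart if all plants entered the cold at the same time, whereas 3 h and 12 h differ from 0 h in clock time as well as in cold. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical. Total estimated counts were between 62.7 and 81.6 M units per library (M, 10 to the power of 6). The spacing of the lowest values puts 1 fragment at about 3.73 units, which gives about 16.8 to 21.9 M fragments per library.

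Libraries of the same cold duration lay close together and the 4 durations lay far apart. Across 16432 tested genes, log2 expression correlated at 0.98 or above among the libraries of the 0, 3 and 12 h groups, and at 0.9615 to 0.9765 among the 24 h libraries. Between 0 h and 24 h libraries the correlation was 0.7922 to 0.8001. These correlations are across genes, which are not independent replicates. The 24 h libraries differed more from one another than those of other groups, with a chi-square per degree of freedom of 22.71 to 61.25 over replicate pairs, against 4.04 to 10.68 in the other groups. In an F test over the 3 contrasts against 0 h, 14667 genes (89.3%) changed at 1 or more durations (edgeR quasi-likelihood, adjusted p below 0.05).

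**Figure D1:**
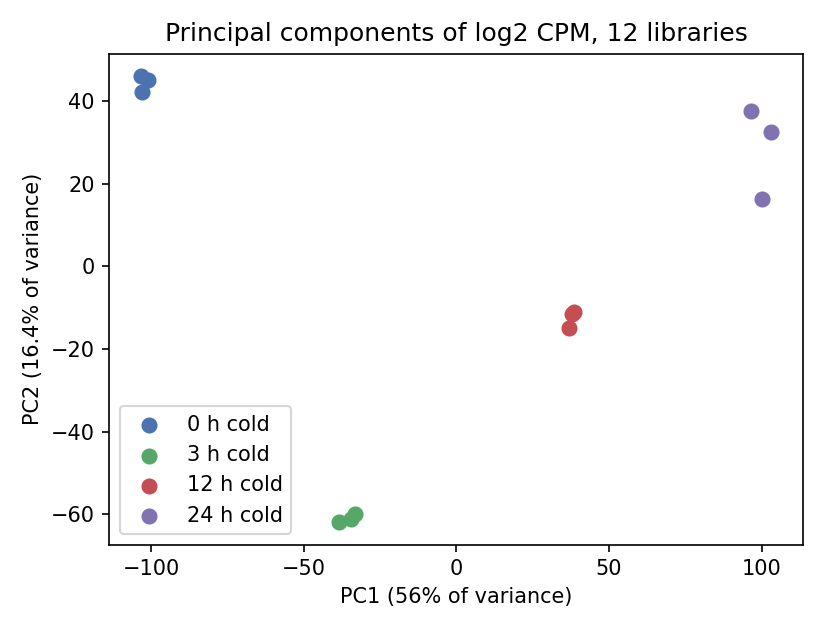
Scores of the 12 libraries on the first principal components of log2 CPM, with PC1 (56% of the variance) on the x axis and PC2 (16.4%) on the y axis; each point is a library, coloured by hours of cold. PC1 runs from -103.3 to -101.1 in the 0 h libraries to between 96.6 and 103.1 in the 24 h libraries, with 3 h and 12 h between them.

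The comparison of 3 h with 0 h asked what changed early in the cold. Among annotated genes with a mean of at least 5 FPKM in the higher group, the steepest rise on the scale of log2(FPKM + 1) was that of GDPD1 (CsaV3_3G026730, chromosome 3, 22977813 to 22980952), a glycerophosphodiester phosphodiesterase, an enzyme of phospholipid breakdown. It rose from 5.34 ± 0.741 to 365 ± 24.6 FPKM (SD, n = 3), a log2 fold change of 6.09 (SE 0.34, edgeR adjusted p = 4.94e-08). On the log2 scale of the fit a weaker gene rose further, an aminocyclopropane carboxylate oxidase homolog of the ethylene list (CsaV3_3G012260), by 6.55 (SE 0.97), from 0.0459 ± 0.0400 to 5.12 ± 2.22 FPKM. SPX domain-containing protein 1 (CsaV3_1G030190, chromosome 1, 16941555 to 16944650), of a family of phosphate sensors, rose from 8.04 ± 1.88 to 379 ± 5.29 FPKM. An inorganic pyrophosphatase 2-like gene (CsaV3_7G034880) rose by 5.27 (SE 0.25) on the log2 scale, phospholipase D p2 (CsaV3_2G006790) by 4.97 (SE 0.22) and monogalactosyldiacylglycerol synthase 2 (CsaV3_2G003280), which makes galactolipids, by 4.41 (SE 0.20). The last of these overlaps a gene on the opposite strand, as does the GDAP2-like gene CsaV3_2G024530, which rose by 4.75 (SE 0.28). Whether counting used strand is not given in the sources used here, so reads of overlapping genes cannot be told apart. The steepest falls included CONSTANS-LIKE 6 (CsaV3_6G003540), a zinc finger regulator of a family tied to day length, from 364 ± 14.4 to 35.2 ± 2.18 FPKM. The chaperone dnaJ 11-like gene CsaV3_2G015850 fell from 61.0 ± 11.2 to 4.02 ± 1.91 FPKM, and a CCCH zinc finger 23-like gene (CsaV3_4G035420), trichome birefringence-like 19 (CsaV3_5G038980), a CLC-b-like chloride channel (CsaV3_2G034160, overlapping an opposite-strand gene) and the CBS domain protein CBSX5 (CsaV3_1G012170) had log2 changes of -4.33, -3.59, -3.56 and -3.40.

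Of the lists fixed beforehand, 4 stood apart from other genes at 3 h in the edgeR fit. Of 60 heat shock proteins and heat stress factors, 38 rose and 1 fell, and the counts adjusted over the list alone were also 38 and 1 (camera adjusted p = 4.28e-06, adjusted p = 0.431 with an estimated correlation). The A-6b-like heat stress factor CsaV3_7G027860 rose from 4.58 ± 0.541 to 67.6 ± 5.62 FPKM. Of 46 photosystem and light-harvesting genes, 31 rose and 3 fell (32 and 4 adjusted over the list alone; camera adjusted p = 2.09e-07, adjusted p = 0.440 with an estimated correlation), among them chlorophyll a-b binding protein 6A (CsaV3_5G025740), from 62.5 ± 4.83 to 367 ± 15.4 FPKM. Of 9 ZAT zinc finger regulators, 7 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00661, adjusted p = 0.431 with an estimated correlation), and this call ended when only the 0 h and 3 h libraries were fitted (adjusted p = 0.0691). Of 21 CBF/DREB and cold-regulated genes, 10 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00855, adjusted p = 0.431 with an estimated correlation), and this call ended with limma on log2(FPKM + 1) (adjusted p = 0.144). Of 44 plastid ribosomal proteins, 22 rose and 4 fell (23 and 4 adjusted over the list alone), which was not called (camera adjusted p = 0.0951) but was with limma on log2(FPKM + 1), the test first designed (adjusted p = 0.00692). The CBF/DREB and cold-regulated list also holds sugar transporters named ERD6-like, which move sugar across membranes. Single members of other lists changed strongly. The kinase CIPK7 (CsaV3_2G013250), of the calcium list, rose by 4.77 (SE 0.27), expansin-A5 (CsaV3_5G038140) by 3.69 (SE 0.23) and a phenylalanine ammonia-lyase-like gene (CsaV3_6G014060), the entry enzyme of phenylpropanoid synthesis, by 3.08 (SE 0.27). In the housekeeping list, which was not called (camera adjusted p = 0.32), a polyubiquitin-like gene (CsaV3_1G011020, overlapping an opposite-strand gene), whose product tags proteins for breakdown, rose by 3.58 (SE 0.14). The starch-phosphorylating alpha-glucan water dikinase (CsaV3_5G031320) had a log2 change of -2.08 (SE 0.20). None of the lists of epidermis, phloem, guard cell or root-type genes was called at 3 h (camera adjusted p = 0.539, 0.544, 0.262 and 0.964). In all, 9481 of 16432 genes changed, 4833 upward and 4648 downward, and 3269 of them by at least 2-fold.

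The comparison of 12 h with 0 h asked what had changed within the first day. The pseudo-response regulator APRR3 (CsaV3_5G000090, chromosome 5, 54545 to 59025) rose from 2.79 ± 0.365 to 338 ± 5.55 FPKM, a log2 fold change of 6.97 (SE 0.16, edgeR adjusted p = 3.29e-11), and a GIGANTEA-like gene (CsaV3_6G005020, chromosome 6, 4242681 to 4253277), an evening component of the clock, from 4.26 ± 0.0917 to 285 ± 6.57 FPKM. Among genes under the same rule of description and level, the largest rise on the scale of log2(FPKM + 1) was that of a DnaJ B6-like co-chaperone (CsaV3_5G028590), from 0.134 ± 0.126 to 418 ± 24.0 FPKM. A cytochrome P450 gene (CsaV3_6G043630), a rop guanine nucleotide exchange factor 5 (CsaV3_6G001490) and a JMJD5-like demethylase (CsaV3_1G042600, overlapping a same-strand gene) rose by 6.56, 7.50 and 7.63 on the log2 scale. The rop factor and the demethylase started low, at means of 0.397 and 0.297 FPKM at 0 h. The root phototropism protein 3-like gene CsaV3_1G039050 fell from 101 ± 7.69 to 0.520 ± 0.0717 FPKM. CONSTANS-LIKE 6 (CsaV3_6G003540) was at 13.4 ± 0.467 FPKM, CONSTANS-LIKE 2-like (CsaV3_4G009980) fell from 870 ± 22.9 to 57.6 ± 9.60 FPKM, and the bHLH35-like regulator CsaV3_2G008770 from 187 ± 8.91 to 9.57 ± 2.41 FPKM.

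At 12 h, 10 lists stood apart. Of 46 photosystem and light-harvesting genes, 27 rose and 4 fell (28 and 4 adjusted over the list alone; camera adjusted p = 9.59e-10, adjusted p = 0.325 with an estimated correlation), and the LHCII type 1-like protein CsaV3_1G032510 rose from 42.0 ± 0.697 to 938 ± 108 FPKM. Of 60 heat shock genes 38 rose and 7 fell (38 and 8 adjusted over the list alone; camera adjusted p = 4.80e-07, adjusted p = 0.325 with an estimated correlation), with heat stress factor A-6b (CsaV3_3G012910) going from 1.28 ± 0.386 to 76.4 ± 5.44 FPKM. Of 152 cytosolic ribosomal proteins 94 rose and 15 fell, also when adjusted over the list alone (camera adjusted p = 0.00276, adjusted p = 0.959 with an estimated correlation), with 60S L27-3-like (CsaV3_4G032310) up by 1.27 (SE 0.10). Of 44 plastid ribosomal proteins 30 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0252, adjusted p = 0.959 with an estimated correlation); this call ended without 0 h replicate 3 (adjusted p = 0.0568) and with only the 2 groups fitted (adjusted p = 0.0745). Of 21 CBF/DREB and cold-regulated genes 12 rose and 4 fell, of 9 ZAT regulators 6 rose and 1 fell, of 36 NAC factors 19 rose and 4 fell and of 9 cold RNA-binding proteins 7 rose and 1 fell (camera adjusted p = 1.16e-05, 0.00735, 0.00804 and 0.00873, adjusted p = 0.148, 0.148, 0.148 and 0.425 with an estimated correlation). Adjusted over the list alone these counts were the same except for ZAT, where 7 rose. Of 31 glutathione S-transferases 17 rose and 5 fell, and of 19 clock genes 9 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0135 and 0.00235, adjusted p = 0.596 and 0.148 with an estimated correlation). With limma on log2(FPKM + 1) the calls of these last lists ended (adjusted p = 0.0547 and 0.445). Among single members of other lists, the ethylene-responsive factor ERF053 (CsaV3_7G004340) rose by 8.56 (SE 0.38), the calmodulin-like protein CML19 (CsaV3_1G000650) by 5.05 (SE 0.54), and the auxin transporter-like protein 2 (CsaV3_3G034000) fell from 84.4 ± 5.02 to 5.12 ± 0.430 FPKM. ERF053 and CML19 had about 12.6 fragments each over the 0 h libraries (means of 0.0788 and 0.350 FPKM). The size of their rises thus rests on few fragments. The epidermis, phloem, guard cell and root-type lists were not called (camera adjusted p = 0.757, 0.996, 0.571 and 0.876). In all, 11069 genes changed, 5652 upward and 5417 downward, 4845 of them by at least 2-fold.

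**Figure D2:**
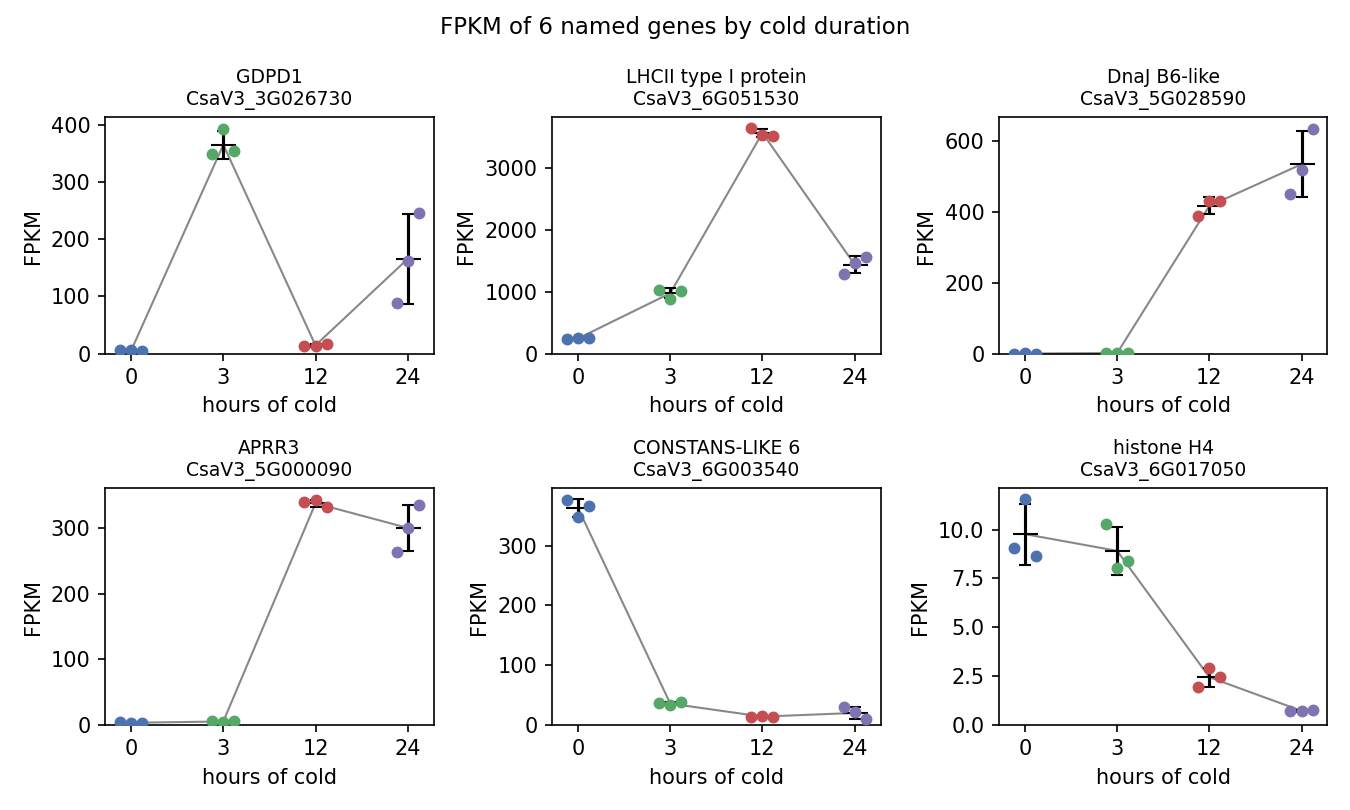
FPKM (y axis, linear from 0) against hours of cold (x axis, evenly spaced categories) for 6 named genes; points are single libraries set side by side, horizontal marks and bars are the mean ± SD of 3, and lines join the means. GDPD1 stood at 365 FPKM at 3 h, 14.4 at 12 h and 165.5 at 24 h. The LHCII type I protein peaked at 3575 at 12 h, and APRR3 was at 338 at 12 h and 300.4 at 24 h.

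The comparison of 24 h with 0 h asked what had changed after a whole day of cold. The DnaJ B6-like gene (CsaV3_5G028590) stood at 536 ± 93.8 FPKM and APRR3 (CsaV3_5G000090) at 300.4 ± 35.7 FPKM. The glutathione S-transferase U8-like gene CsaV3_4G025770 (chromosome 4, 15158782 to 15164631) rose from 1.22 ± 0.416 to 162 ± 37.5 FPKM, a log2 fold change of 7.12 (SE 0.38, edgeR adjusted p = 6.96e-09), and ethylene-responsive transcription factor 6 (CsaV3_3G002470, chromosome 3, 1991077 to 1992111) from 4.75 ± 0.903 to 360.4 ± 4.34 FPKM. An RNA polymerase V subunit 7-like gene (CsaV3_3G012620) and an F-box gene (CsaV3_6G038430) rose by 7.12 (SE 0.35) and 9.66 (SE 0.36). The F-box gene had about 14.7 fragments over the 0 h libraries (mean of 0.106 FPKM), so the size of its rise rests on few fragments. The steepest falls under that rule included those of the root phototropism protein 3-like gene CsaV3_1G039050 (-5.97, SE 0.25), the bHLH35-like regulator CsaV3_2G008770 (-5.50, SE 0.20) and a 21 kDa protein-like gene (CsaV3_5G028280, -5.40, SE 0.16). Pectate lyase 5 (CsaV3_1G009130), which cuts pectin, fell from 151 ± 11.3 to 3.15 ± 0.636 FPKM. A pair of CIPK14-like kinase genes on opposite strands of 1 scaffold (CsaV3_UNG100740 and CsaV3_UNG100750) also fell, and since they overlap, their reads cannot be told apart.

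At 24 h, 9 lists stood apart. Of 152 cytosolic ribosomal proteins 111 rose and 8 fell (camera adjusted p = 3.92e-04, adjusted p = 0.631 with an estimated correlation), among them 40S SA-like (CsaV3_6G002760), by 1.26 (SE 0.06). Of 60 heat shock genes 37 rose and 15 fell (camera adjusted p = 2.60e-05, adjusted p = 0.381 with an estimated correlation), with A-6b (CsaV3_3G012910) at 67.7 ± 3.75 FPKM. Of 21 CBF/DREB and cold-regulated genes 13 rose and 4 fell, of 9 ZAT regulators 6 rose and none fell, of 36 NAC factors 18 rose and 6 fell, and of 9 cold RNA-binding proteins 7 rose and none fell (camera adjusted p = 9.72e-05, 3.29e-04, 0.00415 and 0.00674, adjusted p = 0.133, 0.0934, 0.133 and 0.381 with an estimated correlation). Of 31 glutathione S-transferases 16 rose and 8 fell, of 19 clock genes 8 rose and 6 fell, and of 95 calcium signalling genes 50 rose and 26 fell (camera adjusted p = 0.00627, 0.00283 and 0.0211, adjusted p = 0.381, 0.0934 and 0.381 with an estimated correlation). The calls of these last lists ended with limma on log2(FPKM + 1) (adjusted p = 0.0625, 0.298 and 0.0669), and that of the calcium list also with only genes of mean FPKM at or above 5 (adjusted p = 0.0829). Adjusted over the list alone the counts of the called lists were the same, except that 17 glutathione S-transferases rose and 9 fell. Of 46 photosystem and light-harvesting genes 18 rose and 27 fell (18 and 28 adjusted over the list alone), with no call for the list (camera adjusted p = 0.433), although the LHCII type I protein CsaV3_6G051530 was still at 1443 ± 142 FPKM against 245 ± 9.92 at 0 h. Of 69 histone and DNA replication genes 18 rose and 38 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0551). It was called under other settings, such as without a filter on low values (adjusted p = 0.02). Histone H4 (CsaV3_6G017050) fell from 9.77 ± 1.57 to 0.704 ± 0.0521 FPKM. A xyloglucan endotransglucosylase/hydrolase (CsaV3_1G031460), which remodels cell walls, rose by 6.07 (SE 0.15), CML19 (CsaV3_1G000650) by 7.78 (SE 0.57, from a low 0 h mean of 0.350 FPKM), and a phenylalanine ammonia-lyase-like gene (CsaV3_6G039710) by 5.91 (SE 0.59). ERF098-like (CsaV3_2G012880) had no count in any 0 h library and was at 2.21, 3.15 and 27.0 FPKM in the 24 h libraries. A single library thus carried most of its mean. The epidermis, phloem, guard cell and root-type lists were not called (camera adjusted p = 0.185, 0.523, 0.533 and 0.618). In all, 12188 genes changed, 5955 upward and 6233 downward, 6152 of them by at least 2-fold. The fit shares its estimate of spread over all groups, although the 24 h libraries spread more. With only the 2 groups compared in the fit, 11215 genes changed at 24 h and 11789 at 12 h. Whether more genes changed at 24 h than at 12 h thus depends on the fit.

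The comparisons between cold durations asked what changed further. From 3 h to 12 h, 9127 genes changed (4591 up, 4536 down). Of 19 clock genes 8 rose and 4 fell (9 and 4 adjusted over the list alone), a call that held with an estimated correlation (camera adjusted p = 6.82e-05, adjusted p = 0.0397 with an estimated correlation). List calls between cold durations were not rerun with limma on log2(FPKM + 1), other scalings or left-out libraries. The calls of the clock list against 0 h ended with that limma fit. Of 152 cytosolic ribosomal proteins 103 rose and 3 fell between those times (106 and 5 adjusted over the list alone; camera adjusted p = 6.82e-05, adjusted p = 0.857 with an estimated correlation). Which direction held more genes depended on scaling, filter or test in every comparison. Neither direction can thus be said to prevail. From 3 h to 12 h, 3908 genes rose and 5416 fell with limma on FPKM rescaled to equal totals. At 12 h against 0 h, 5294 rose and 5944 fell with limma on log2(FPKM + 1), at 3 h 4581 and 5098 with quantile scaling, and at 24 h 6149 and 6006 with median-of-ratios scaling. From 12 h to 24 h, 8531 genes changed (4021 up, 4510 down). Of 46 photosystem and light-harvesting genes 39 fell and 7 rose, also when adjusted over the list alone (camera adjusted p = 1.66e-34, adjusted p = 0.1001 with an estimated correlation). Of 44 plastid ribosomal proteins 27 fell and 1 rose, and of 20 aquaporins, the water channels of membranes, 12 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 8.51e-04 and 8.76e-04, adjusted p = 0.457 and 0.239 with an estimated correlation). From 3 h to 24 h, 11116 genes changed (5520 up, 5596 down). Of 83 cell wall genes 45 fell and 20 rose, and of 64 cuticle and wax genes, a list of epidermis genes, 35 fell and 7 rose (46 and 20, and 35 and 7, adjusted over the list alone; camera adjusted p = 0.00971 in each, adjusted p = 0.283 and 0.445 with an estimated correlation).

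By the tests at 3 h and 24 h, 1894 genes rose by 3 h and were lower again at 24 h than at 3 h, and 1705 did the opposite. A further 1071 were higher and 1296 lower than 0 h at both times without a passing difference between these, which does not show that the level stayed equal. Late changes, seen at 24 h against both 0 h and 3 h but not at 3 h against 0 h, comprised 1904 rises and 1973 falls. The 12 h libraries did not enter these classes, so that such a change may have been present by 12 h. The photosystem list held 20 genes of the first kind, the cytosolic ribosomal list 46 late rises, and the clock list 8 genes that fell by 3 h and were higher at 24 h than at 3 h. Changes against 0 h overlapped between durations. At 12 h and 24 h, 4422 genes rose at both times and 4367 fell at both, against 2048 and 2055 for independent lists and 0 with simulated unchanged groups. At 3 h and 24 h, 3177 rose and 3180 fell at both times, against 1751 and 1763 for independent lists and 0 in the simulation, and at 3 h and 12 h 3336 and 3253, against 1662 and 1532, and 0. The covariance of log2 fold changes across genes was 1.799 for 12 h and 24 h, 1.106 for 3 h and 24 h and 0.945 for 3 h and 12 h, and 0.045, 0.045 and 0.046 with simulated unchanged groups. The correlations were 0.81, 0.62 and 0.66, against 0.5, 0.49 and 0.51. The simulated overlaps of 0 decide nothing, since at most 0.1 genes per comparison were called there on average. All comparisons share the 0 h libraries, which at 3 could not be split into parts of at least 2. Part of the excess of the overlaps over independent lists may thus come from them.

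Annotation terms given in the file were tested in the same way. Photosynthesis light harvesting was raised at 3 h and 12 h, with 16 of 19 members up at each time (camera adjusted p = 2.35e-14 and 5.87e-22, adjusted p = 0.999 and 0.467 with an estimated correlation). Ribosome biogenesis was raised at 12 h and 24 h, with 181 and 183 of 297 members up (camera adjusted p = 0.0108 and 0.0374, adjusted p = 0.989 and 0.986 with an estimated correlation). At 24 h the term photosynthesis had 30 of 39 members down and the nucleosome term 29 of 40 (camera adjusted p = 2.25e-04 and 0.0114, adjusted p = 0.986 in each with an estimated correlation). Of 477 terms, 7 were called at 3 h, 13 at 12 h and 10 at 24 h with the preset correlation, and 0 of these with an estimated one.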

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

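The tests on phosphate-related families, on clock genes and on sequencing depth were chosen only after the result was seen; those on position in the cold response and on transcript length, and the other splits of the libraries, were written down before their results were seen.

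Some genes passed the tests against 0 h in opposite directions at different durations: 1300 at 3 h and 24 h, 768 at 3 h and 12 h, and 491 at 12 h and 24 h. They stand out because the effect differs between time points. Of the genes named, the chaperone dnaJ 11-like gene (CsaV3_2G015850) was below 0 h at 3 h (log2 fold change -3.92) and at 12 h (-2.13) and above it at 24 h (2.63). The difference between the effects was 6.55 (SE 0.50, edgeR adjusted p = 2.47e-07) for 24 h against 3 h and 4.76 (SE 0.45, adjusted p = 4.67e-06) for 24 h against 12 h. Its 24 h level spread widely, at 363 ± 190 FPKM (SD, n = 3).

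Among families known from phosphate starvation (58 tested genes), 35 rose and 8 fell at 3 h, with a median log2 fold change of 0.58 (camera p = 7.47e-09, p = 0.002 with an estimated correlation). The list passed no test at 12 h (27 rose, 14 fell, camera p = 0.156, p = 0.273 with an estimated correlation), 29 fell and 11 rose from 3 h to 12 h, and at 24 h 31 were above 0 h and 13 below (p = 0.0182, p = 0.0958 with an estimated correlation). This list was written after the fold changes of all its members had been printed. Its p-values, and that of the 53 genes left without the largest rises (camera p = 3.64e-05 with the preset correlation), are thus no independent evidence. A narrower choice of 44 genes gave a median of 1.12 at 3 h. At 12 h that choice passed with the preset correlation only (23 rose, 10 fell, camera p = 0.0306, p = 0.198 with an estimated correlation). The lack of a call at 12 h thus depends on the genes chosen. Scaling by library totals and by median of ratios gave medians of 0.60 and 0.59 but put the median of all genes at only 0.017 and 0.008, so that rerunning with them decides nothing. A factor per library moves all genes alike, yet the median at 3 h was 0.58 in the families and 0.001 over all genes. Without the largest rises the families' median was 0.532. This argues against scaling as the source of the difference between these families and other genes. A pattern read from its own top genes, root RNA and time of day alone cannot be told apart from an effect of cold. Of only 8 root-type genes 25% rose. Of the risen members 68.6% were also above 0 h at 24 h, but they were picked against the same 0 h libraries. Over all tested genes a like share held, with 3177 of the 4833 risen at 3 h also above 0 h at 24 h. The share thus tells little about these families. Leaves of sprayed seedlings kept warm until the same clock times would test an effect of cold.

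Of 19 clock genes, 14 differed from 0 h at 24 h, a share near the 74.2% of all tested genes that changed then. Over all 19 the median absolute log2 fold change was 1.19 at 12 h and 0.87 at 24 h. Over all tested genes it was 0.614 and 0.739, so by these measures the clock genes stood out at 12 h but little at 24 h. The 15 clock genes that had changed at 12 h, a choice made against the same 0 h libraries, gave 1.33 and 1.91. Time of day alone cannot be told apart, since the clock time of sampling is not given in the sources used here. An exchange of single libraries between 12 h and 24 h is argued against, since each 24 h library correlated better with the others of its group than with any at 12 h, by at least 0.0279. An exchange of the whole groups and an effect of cold stay open, and leaves of sprayed seedlings kept warm until the same clock times would test the latter.

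The 24 h libraries spread more than those of other groups. Transcript length is argued against by a rank correlation of -0.05 between the difference of replicates 1 and 3 and length, and depth by a difference of 2.2 M fragments (M, 10 to the power of 6), under the range of 3.8 M among 0 h libraries. Whether the libraries stood at different points of the cold response cannot be told apart, since the correlation of that difference with the step from 12 h was 0.19, between the bounds set beforehand.

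With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; only 1 split, the real one, called as many genes in each comparison. The real counts were 9481, 11069 and 12188 for 3, 12 and 24 h against 0 h, 9127 for 12 h against 3 h, 8531 for 24 h against 12 h and 11116 for 24 h against 3 h. The highest counts of the other splits were 1, 1, 0, 1, 0 and 0. For a change at any duration, 1 of 100 splits of the 12 libraries, the real one, reached 14667, and the highest other count was 10034. This argues against a chance assignment of libraries to durations. It does not cover chance differences between plants, since the labels do not say whether the libraries came from separate plants. The split with 10034 genes kept together 8 of the 12 pairs of libraries of a real group, against a median of 2 over the other splits. What gave its count was not tested.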

How the results depend on the processing

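The fits with limma on log2(FPKM + 1), with DESeq2 and on counts divided by 3.73 were chosen only after the data were seen. No list or named gene called against 0 h reversed under any alternative run. List calls between cold durations were not rerun with other tests, scalings or left-out libraries. The larger of rises and falls did turn with scaling, filter or test in every comparison, by up to 8.4 points in the percent of rises, and up to 10 single called genes of a comparison changed sign with quantile scaling. In 2101 values of the 78 named gene and comparison pairs no call was lost. These genes were chosen as called and strongly changed in the same libraries, so that little could be lost. Counts of changed genes stayed within 1.5 times except with a 2-fold threshold, which is stricter by construction and gave 3269 (3 h against 0 h), 4845 (12 h against 0 h), 6152 (24 h against 0 h), 3147 (12 h against 3 h), 2865 (24 h against 12 h) and 4855 (24 h against 3 h). With a mean of at least 5 FPKM, where fewer genes are tested, 691 genes were higher at both 3 h and 24 h without a passing difference, and 1242 fell late. Leaving out 1 library at a time gave 8475 to 10215 genes for 3 h against 0 h, 10189 to 11650 for 12 h, 11483 to 12221 for 24 h, 7869 to 9867 for 12 h against 3 h, 7298 to 9132 for 24 h against 12 h, 10204 to 11162 for 24 h against 3 h and 14229 to 14844 for any duration. Likewise 1620 to 2083 genes rose and were lower again at 24 h than at 3 h, 1421 to 1870 did the opposite, 927 to 1148 and 1161 to 1368 were higher or lower at both times, and 1683 to 2106 rose and 1755 to 2129 fell late. With the replicate number as a block the counts were 9306, 10939, 12063, 8921, 8348 and 10991, and 14535 for any duration. The replicate numbers showed no shared effect. Deviations from the group mean correlated across genes at -0.07 to 0.09 between same-numbered libraries in 18 pairs. By these deviations 3 of 12 libraries were closest to their own number. With 3 libraries per group this does not show that the samples were unpaired. With DESeq2 the counts were 9810, 11294 and 12308 against 0 h, and with limma on log2(FPKM + 1) 9641, 11238 and 12286. Fits of only the 2 groups compared gave 10480, 11789 and 11215 against 0 h, and 7033 for 24 h against 12 h. Of 120 list and comparison pairs against 0 h, 23 were called and 0 of these held with an estimated correlation, while 15 were lost under no other alternative. A further 10 pairs were called only under some alternative, 6 at 3 h (glutathione S-transferases, phenylpropanoids, proline, fatty acid desaturation, WRKY factors and plastid ribosomal proteins) and 4 at 24 h (ethylene, MAP kinases, WRKY factors and histones).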

Other observations

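The split of the photosystem list, and the genes named here, were chosen only after their values were seen, so all tests in this part came after the result. Of 18 light-harvesting antenna genes, 16 rose and none fell at 3 h (median log2 fold change 1.36) and at 12 h (2.44; camera p = 1.54e-28, p = 0.00149 with an estimated correlation), and 12 rose and 6 fell at 24 h (0.98). A second set held 22 genes of photosystem subunits and electron transport, without the core proteins photosystem II D1 and D2 and CP47. Of these 22, 9 rose and 3 fell at 3 h (0.01), and 10 rose and 4 fell at 12 h (0.18). At 24 h none rose and 21 fell (-0.81, camera p = 6.95e-08, p = 0.0695 with an estimated correlation). From 12 h to 24 h both sets fell, 18 of 18 antenna genes (-1.46, camera p = 0.00138 with an estimated correlation) and 21 of 22 genes of the second set (-1.24, camera p = 0.00381 with an estimated correlation). The other 6 genes of the list, among them photosystem II D1 and D2 and CP47, were in neither set, and all 6 rose at 3 h, 1 at 12 h, and all 6 at 24 h and from 12 h to 24 h. The difference between the sets was not tested.

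Of the CBF/DREB and cold-regulated list, members named DREB, regulators of cold and drought genes, were not tested as a group. The DREB2A-like genes CsaV3_4G026790 and CsaV3_4G026910 went from 2.58 ± 0.323 and 4.10 ± 0.276 FPKM at 0 h to 13.6 ± 1.20 and 19.6 ± 0.671 at 3 h, 23.6 ± 1.60 and 30.7 ± 0.333 at 12 h and 39.8 ± 3.25 and 46.0 ± 2.53 at 24 h (SD, n = 3), whereas another DREB2A-like gene (CsaV3_6G012590) passed no test against 0 h. DREB1B-like (CsaV3_5G005890) was at 0.384 ± 0.253, 0.715 ± 0.345, 0.521 ± 0.294 and 15.3 ± 5.47 FPKM at 0, 3, 12 and 24 h, and DREB1A (CsaV3_3G016760) at 1.503 ± 0.365, 0.450 ± 0.171, 2.95 ± 1.22 and 13.0 ± 3.93 FPKM. Among clock genes, LHY-like (CsaV3_6G008360), a morning component, went from 555 ± 19.0 FPKM at 0 h to 142 ± 21.1 at 24 h. APRR7 (CsaV3_4G024430) went from 5.81 ± 0.291 to 41.2 ± 3.98 at 3 h and 168 ± 33.0 at 24 h, and adagio protein 3 (CsaV3_5G014370), a blue light receptor, from 1.29 ± 0.00987 to 45.1 ± 0.570 at 12 h.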
